A study of Mus musculus with 31 samples.

How the data were processed

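RNA from 31 samples of colon scrapings of male C57Bl/6J mice was hybridised, 1 array per sample, to single-colour whole-transcript arrays. The authors supplied log2 values made by RMA, which corrects the background, normalizes quantiles across arrays and summarises probes to probe sets. The version of RMA and the genome build behind the array design are not given in the sources used here. The values ran from 1.13 to 13.8, with array medians of 5.14 to 5.19. The signal over background of each array limits what can be told of dim genes, and no depth applies.

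Of the probe sets 23099 are listed in the annotation used, 21218 with 1 gene symbol and 1881 with several, and 12457 are not listed. Probe sets with 1 symbol were kept, and of the 1386 genes (of 18820) with more than 1 the probe set with the highest mean was taken. A gene was tested when at least 3 arrays reached an intensity of 20, which left 12795 genes. Gene names came from the annotation and a gene table of the mouse, which was also used to find genes that host small nucleolar RNAs.

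A linear model with 1 mean per group (8 groups, 31 arrays) was fitted with limma 3.58.1 in R 4.3.3, with variances moderated along an intensity trend. It gave 17 comparisons: diet over all 4 infusions, diet under saline, each acid against saline on each diet, the difference of each acid's response between the diets, and the acids against each other on each diet. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over the genes of a comparison. Standard errors are those of the moderated fit, and the error of a list's mean comes from the array means of its members. Both pool the spread over the 8 groups, so they are too small where the groups compared vary more than most.

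Of 40 gene lists of functions and cell types, the 39 with at least 4 tested members were tested with camera at a preset correlation between genes of 0.01, with the adjustment over the lists of a comparison. Beside it stand camera with an estimated correlation and the rotation test fry. Members were also adjusted over the list alone. The groups, comparisons, lists, thresholds and the rule for naming genes were fixed before the data were examined.

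The genes named are, in each comparison, the 10 with the largest rise and the 10 with the largest fall among those past the threshold. Where fewer than 10 passed, they are the 10 with the smallest p. Members of lists that passed over all genes or over the list alone (up to 6 per list), up to 4 members of a list called by camera, and a fixed panel of acid targets were added. Gene models without a descriptive name and small RNAs were counted and not named. The small nucleolar RNAs as a set were added after their values were seen. A further gene of the panel is not reported here.

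Responses were correlated between diets across genes, with an exact permutation of the acid and saline arrays within each diet, two-sided. Responses that share saline arrays were set against 1000 simulations in which residuals of randomly drawn arrays stood for unchanged groups and for the controls they share, and against splits of the saline arrays into pairs. The replicate numbers were checked for pairing by the correlation of deviations from the group means. An array was singled out when its gap to the nearest of its group of 4 exceeded the 95% critical value of Dixon's test. Counts were compared with those from other splits of the same arrays, at most 100.

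The code was tested on simulated data: normal values were drawn with the mean and residual spread of each of the 12795 genes, independently between genes, and 200 genes were shifted. Of genes shifted by a log2 of 0.25, 0.5 and 1, it recovered 67.2%, 100% and 100% for diet over all infusions, 11.9%, 65.7% and 97% for propionate on HFD, 5.97%, 61.2% and 93.9% for butyrate against propionate on HFD, and 10.4%, 70.1% and 97% for acetate on LFD, without a wrong sign. Genes called without a shift numbered 16, 2, 2 and 4.

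The alternatives were no filter, a stricter filter (mean log2 level of at least 6, 8751 genes), moderation without the trend or robust, array weights, all probe sets, quantile normalization, the replicate number as a block, only the groups compared, and leaving out each array. Leaving out the 4 arrays high in small-intestinal transcripts, leaving out the 2 saline HFD arrays high in smooth muscle transcripts, and the small nucleolar RNA mean as a covariate were chosen after seeing the data. So were the means of called lists recomputed without these arrays and without each array. The markers of red blood cells had too few tested members for a list test.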

Results

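Gene expression was measured in scrapings of the colonic lining of male C57Bl/6J mice on single-colour arrays. The mice ate a low-fat diet (LFD, 10% of energy from fat) or a high-fat diet (HFD, 45%). On 6 consecutive days they received a rectal infusion of 80 µL of saline, alone or with 100 mM sodium acetate, propionate or butyrate, and the colons were taken 4 h after the last infusion. Acetate, propionate and butyrate are short-chain fatty acids, linear carboxylic acids of increasing chain length that gut bacteria make from fibre. Each group had 4 arrays (n = 4), except acetate on LFD with 3 (n = 3), 31 arrays in all. The labels name 6 mice per group and do not say which of them the arrays hold. Array medians lay between 5.14 and 5.19 on the log2 scale, and arrays of a group correlated with an r of 0.981 to 0.994. After a filter on dim probe sets, 12795 genes were tested. Values below are log2 differences ± the standard error of the fit, and the number of arrays limits their precision. Counts such as 4 of 4 arrays give the arrays on that side of the mean of the group compared with. For diet this is the LFD group with the same infusion. Such counts do not mean that the groups stand apart without overlap.

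Certain arrays stood apart in some sets of transcripts. Transcripts of lipid absorption and lipoprotein assembly (15 genes, Apoa1, Apoa4 and Mttp among them) had a mean log2 level of 7.89 to 8.12 on 4 arrays, saline LFD 2 and 3, propionate LFD 2 and saline HFD 2, and at most 7.03 on the others. Smooth muscle transcripts (10 genes, such as Myl9, Tagln and Des) averaged 6.76 and 6.56 on saline HFD 1 and 2 and at most 6.02 elsewhere. The 55 small nucleolar RNAs tested, which guide the modification of ribosomal RNA, averaged 7.75 ± 0.249 (SD, n = 4) under propionate on HFD and at most 7.34 in the other 7 groups, though saline LFD 1 (7.79) and acetate LFD 1 (7.58) lay above propionate HFD 4 (7.40). Several list means below rest on such arrays or on 1 array, and the value without them is then given.

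**Figure D1:**
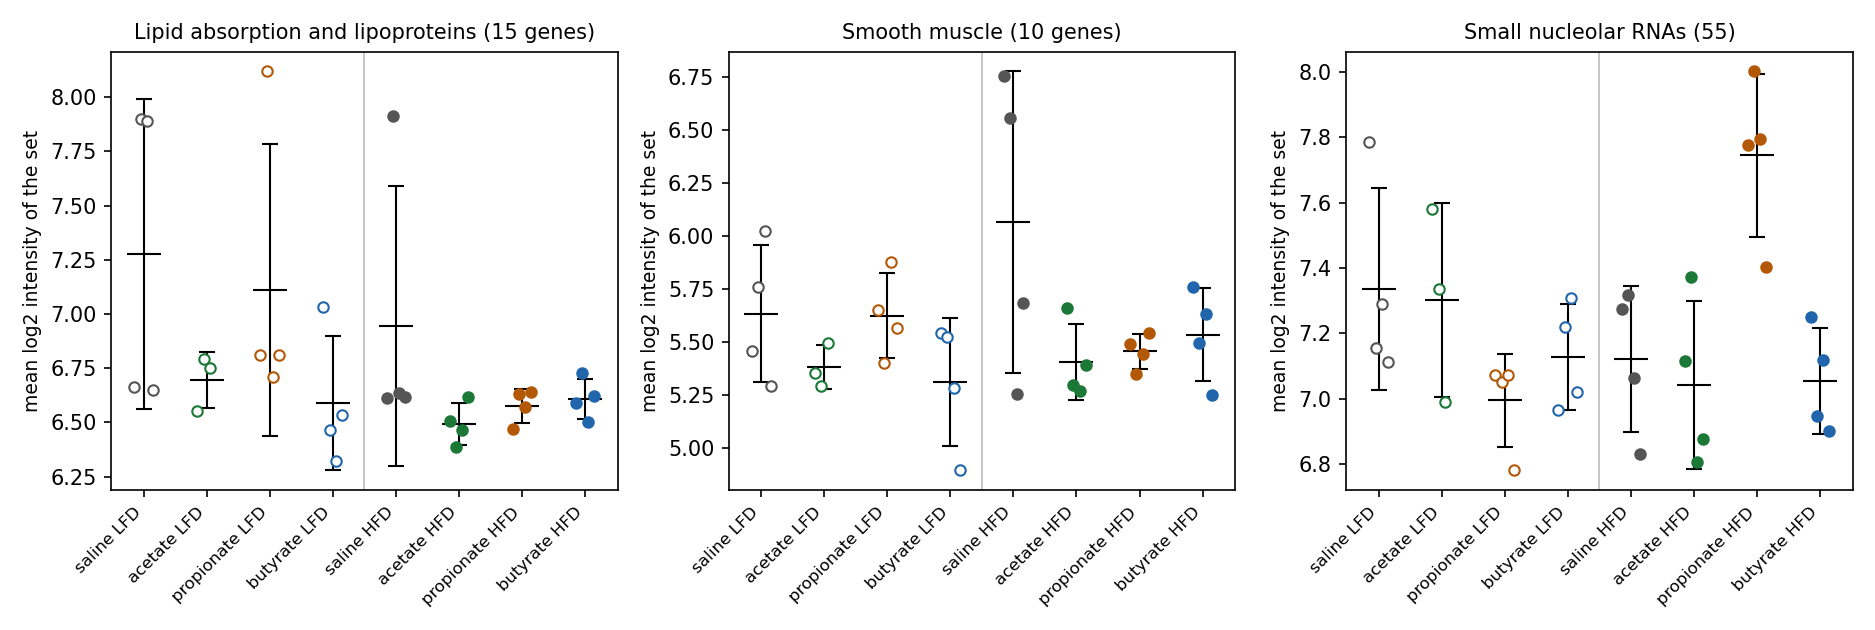
Mean log2 intensity of 3 gene sets on each of the 31 arrays (y axis) by infusion and diet (x axis); points are arrays (open LFD, filled HFD), bars the group mean ± SD. In the lipid absorption set 4 arrays lie between 7.89 and 8.12, in the smooth muscle set 2 saline HFD arrays lie at 6.56 and 6.76, and the small nucleolar RNAs average 7.75 under propionate on HFD.

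The first question was what the diet changed, HFD against LFD, taken over all 4 infusions. The share of energy not from fat differs between the diets as well, so fat itself cannot be told apart from the rest of the diet. On HFD the colon expressed less of the enzymes that make fatty acids and cholesterol. Scd1, the desaturase that makes monounsaturated fatty acids (probe set 10467979), fell by 55.2%, a log2 difference of -1.16 ± 0.15 (adjusted p = 0.000488, lower in 16 of 16 HFD arrays). The fatty acid desaturases Scd2 (-0.66 ± 0.14) and Fads1 (-0.60 ± 0.12) fell as well, as did the sterol enzymes Lss (-0.66 ± 0.13), Sqle (-0.61 ± 0.13) and Idi1 (-0.60 ± 0.14). Depp1 (0.99 ± 0.22), Edn1, which encodes a vasoconstrictor peptide (0.83 ± 0.23), and Cd83, a marker of mature dendritic cells (0.55 ± 0.10), rose in 16 of 16 HFD arrays (adjusted p = 0.0201, 0.0458 and 0.0161).

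Over all infusions limma found 345 genes changed by diet, 196 higher and 149 lower on HFD, with 2779 genes at an unadjusted p under 0.05 where 639.8 are expected by chance. Their changes were small, a median absolute log2 difference of 0.24, and 1 gene, Scd1, changed more than 2-fold. The others with the largest falls were Fabp6, the ileal bile acid binding protein (-0.90 ± 0.22), Mfsd2a, a transporter of lysophosphatidylcholine (-0.79 ± 0.17), the lysophospholipid acyltransferase Lpcat4 (-0.64 ± 0.13) and the chaperone Hsp90aa1 (-0.56 ± 0.15), each lower in 14 to 16 of 16 HFD arrays. Fabp6 stood at -0.87 without the 4 arrays high in small-intestinal transcripts, and missed the threshold over all probe sets. It was not alone in this. Of the 104 genes under the naming rule in this comparison, passing or not, 22 lost their call over all probe sets. Another setting, without the 2 saline HFD arrays high in smooth muscle, cost 13 of the 104 their call. Besides Depp1, Edn1 and Cd83, the largest rises were those of Sun2 (0.68 ± 0.16), Rab33a (0.64 ± 0.14), Sh3d21 (0.60 ± 0.14), Ahnak2 (0.59 ± 0.15), Tmem86a (0.56 ± 0.13), Bnip5 (0.53 ± 0.12) and Ypel3 (0.52 ± 0.11), each in 14 or 15 of 16 arrays.

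By gene list, 12 of the 20 tested genes of cholesterol biosynthesis and uptake fell, 18 when adjusted over the list alone, and all 20 lay below 0. Their mean was -0.36 ± 0.0882 (camera adjusted p = 2.6e-16, lower in 13 of 16 HFD arrays). Among them were Cyp51 (-0.55 ± 0.12), Fdps (-0.49 ± 0.11), Hmgcs1 (-0.52 ± 0.12) and Hsd17b7 (-0.37 ± 0.081). Of the 13 genes of fatty acid synthesis and desaturation, 8 fell (11 adjusted over the list alone), Fasn (-0.35 ± 0.0774), Acaca (-0.27 ± 0.0534) and Elovl5 (-0.27 ± 0.0607) included. Their mean was -0.38 ± 0.0601 (camera adjusted p = 1.21e-11, lower in 16 of 16). With an estimated correlation the adjusted p was 0.247 for the cholesterol list and 0.0671 for the fatty acid list. The rotation test fry, which asks whether the genes of a list move one way, gave adjusted p of 0.00872 and 0.000202.

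Chaperones followed. Of 9 heat shock proteins 3 fell, Hspe1 (-0.37 ± 0.0882), Hspd1 (-0.35 ± 0.0862) and Hsp90aa1, and 6 adjusted over the list alone (mean -0.33 ± 0.10, camera adjusted p = 1.49e-05, lower in 14 of 16). Of 16 genes of the unfolded protein response 3 fell, Creld2 (-0.48 ± 0.12), Hspa5 (-0.41 ± 0.11) and Hyou1 (-0.49 ± 0.13), and 9 adjusted over the list alone (mean -0.21 ± 0.0634, camera adjusted p = 3.27e-06, lower in 13 of 16). Both had adjusted p = 0.304 with an estimated correlation and 0.028 by fry. Antimicrobial defence (mean -0.31 ± 0.0807, camera adjusted p = 0.00176, lower in 14 of 16) had no gene past the threshold over all genes and 6 of 14 adjusted over the list alone, with Retnlb at -0.89 ± 0.29 and Reg3g at -0.98 ± 0.34. Its adjusted p was 0.247 with an estimated correlation and 0.0105 by fry. Glycolysis (mean -0.10 ± 0.0295, 13 of 13 genes below 0, 5 lower adjusted over the list alone) had camera, estimated-correlation and fry adjusted p of 8.41e-05, 0.304 and 0.0227, and was lower in 12 of 16.

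Smaller downward shifts by camera were those of oxidative phosphorylation (mean -0.05 ± 0.0265, adjusted p = 3.12e-06), the cell cycle (-0.14 ± 0.0695, adjusted p = 3.87e-05, with Mcm4 lower at -0.32 ± 0.0881) and the tricarboxylic acid cycle (-0.06 ± 0.0229, adjusted p = 0.00958). Upward shifts were those of fatty acid oxidation (0.07 ± 0.0433, adjusted p = 0.0106, Acadl higher at 0.18 ± 0.0441 and 6 of 20 adjusted over the list alone), targets of the fatty acid receptor PPAR-alpha (0.14 ± 0.0716, adjusted p = 0.018, Slc27a2 higher at 0.45 ± 0.0969 and 6 of 14 adjusted over the list alone), MHC class II (0.22 ± 0.13, adjusted p = 0.0115) and macrophages and dendritic cells (0.14 ± 0.0664, adjusted p = 0.0122). These 7 lists were shifted that way in 10 to 14 of 16 HFD arrays, and none kept its call with an estimated correlation (adjusted p = 0.51 to 0.659) or by fry (0.0999 to 0.291). The 4 arrays lowest in markers of the distal colon were all LFD (5.63 to 5.93, the lowest HFD array 6.12), and these markers averaged 0.17 ± 0.15 higher on HFD (camera adjusted p = 0.296), so the position of the scraping is not fully separated from diet. The count of 345 was 115 without the 2 saline HFD arrays high in smooth muscle, 559 without the 4 arrays high in small-intestinal transcripts, 106 over all probe sets and 1788 with array weights. Leaving out single arrays gave 127 (without acetate LFD 3) to 1027 (without saline LFD 3), and 115 of the 345 genes passed without the 2 saline HFD arrays.

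**Figure D2:**
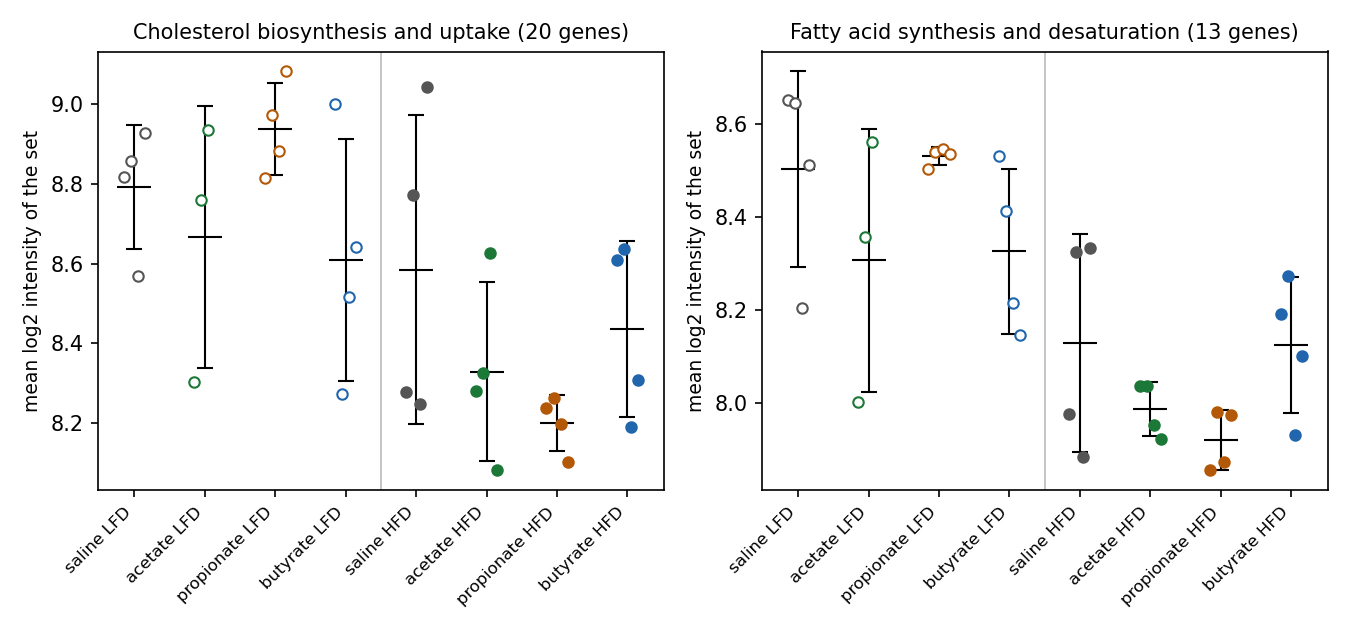
Mean log2 intensity (y axis) of 20 genes of cholesterol biosynthesis and uptake and 13 of fatty acid synthesis and desaturation by infusion and diet (x axis); points are arrays (open LFD, filled HFD), bars the group mean ± SD. The fatty acid list averages 8.31 to 8.53 in the 4 LFD groups and 7.92 to 8.13 in the 4 HFD groups.

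Under saline alone, the same diet question rested on 4 arrays against 4. Scd1 was again the lipid gene that stood out, with a difference of -1.18 ± 0.30 and lower in 4 of 4 HFD arrays, but it did not pass (adjusted p = 0.667). Limma found 0 genes, with 932 at an unadjusted p under 0.05. The 10 smallest p belonged to Cul7, Gpr75, Bok, Ell3, Zfp108, Endov and Lancl1 (higher) and Scd1, Fam136a and Dcun1d1 (lower), each in 4 of 4 arrays. Fatty acid synthesis and desaturation averaged -0.37 ± 0.12 (camera adjusted p = 9.32e-07, lower in 4 of 4), with Scd1, Me1, Elovl5 and Thrsp lower adjusted over the list alone. Saline LFD 1 and 2 were the highest saline arrays in this list (8.65 and 8.645, with saline LFD 3 and 4 at 8.20 and 8.51). They were also the highest saline arrays in adipocyte transcripts (7.14 and 6.87), so adipocyte transcripts are not separated from diet there. Antimicrobial defence averaged -0.49 ± 0.16 (camera adjusted p = 0.00194, lower in 4 of 4) and ion and water transport 0.22 ± 0.13 (camera adjusted p = 0.0202, higher in 4 of 4). In that list Hsd11b2 (0.42 ± 0.12) and Scnn1b, a subunit of the epithelial sodium channel (0.75 ± 0.23), were higher adjusted over the list alone. Of the saline LFD arrays, 1 and 2 were lowest in ion and water transport (9.66 and 9.76) and also low in markers of the distal colon (5.75 and 5.93), so position is not separated from diet there either. Smooth muscle averaged 0.43 ± 0.23 (camera adjusted p = 0.0011), and -0.16 without the 2 saline HFD arrays high in those transcripts. Under the estimated correlation these 4 lists had adjusted p of 0.365, 0.365, 0.691 and 0.691. Of 39 lists 13 were called by camera and none by fry or with an estimated correlation, and without the 4 arrays high in small-intestinal transcripts 2 genes passed.

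The next question was what each acid changed against saline on LFD. Under acetate no gene passed. The 10 smallest p belonged to Mesp2, Fcrlb and Aym1 (higher) and Carhsp1, Pemt, Slc23a4, Birc5, Gdpd3, Fbln5 and Dedd2 (lower), each in 3 of 3 acetate arrays. Among them were Slc23a4 at -0.56 ± 0.17 and the mitotic gene Birc5 at -0.48 ± 0.15. Of 26 cell cycle genes 24 lay below 0 (mean -0.21 ± 0.15, camera adjusted p = 5.73e-10, lower in 2 of 3 arrays). Transcripts of lipid absorption averaged -0.58 ± 0.34 (camera adjusted p = 1.16e-05, lower in 3 of 3), with Npc1l1, the intestinal sterol transporter, at -1.35 ± 0.61. Of the 4 saline LFD arrays 2 are among the 4 high in these transcripts, and without them the mean was 0.0411. Markers of stem and progenitor cells averaged 0.13 ± 0.0824 (camera adjusted p = 0.00217, higher in 3 of 3), and genes of acute inflammation 0.36 ± 0.21 (camera adjusted p = 0.000196, higher in 2 of 3). Without saline LFD 4 the cell cycle mean was -0.12, without saline LFD 1 the stem cell mean 0.0273, and without acetate LFD 1 the inflammation mean 0.0308. The level of the inflammation genes was 4.61 under saline and 4.97 under acetate, near the filter's log2 of 4.32. With an estimated correlation the 4 lists had adjusted p of 0.467, 0.429, 0.467 and 0.429. The count in limma was 0 genes, with 193 at an unadjusted p under 0.05, fewer than the 639.8 expected by chance. Camera called 13 lists, where other splits of the same arrays gave a median of 9. None of the 13 was called by fry or with an estimated correlation.

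Under propionate on LFD all 14 genes that activate and break down short-chain fatty acids lay above 0, with a mean of 0.15 ± 0.056 (camera adjusted p = 7.99e-05, higher in 4 of 4 arrays; adjusted p = 0.655 with an estimated correlation). Echs1, an enzyme of short-chain acyl-CoA breakdown, was at 0.25 ± 0.10, and none passed alone. Ribosomal proteins averaged -0.06 ± 0.0495 (camera adjusted p = 9.22e-05, lower in 4 of 4; adjusted p = 0.916 with an estimated correlation), on arrays where the small nucleolar RNAs averaged -0.34 ± 0.16. Without saline LFD 1 these means were -0.0200 and -0.19. The smallest p belonged to Il7r, the interleukin receptor of lymphocytes (0.46 ± 0.12), Gtf2h4, Dand5, Gsdmcl-ps, Coq2, Adgrg1 and Mageh1 (higher) and Rbis (-0.43 ± 0.10), Pex5 and Tmem151a (lower), each in 4 of 4 arrays. By limma 0 genes changed (smallest adjusted p = 0.972), with 487 at an unadjusted p under 0.05, fewer than the 639.8 expected by chance. By camera 8 lists were called, none by fry or with an estimated correlation.

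Under butyrate on LFD transcripts of lipid absorption averaged -0.69 ± 0.31 (camera adjusted p = 3.58e-08, lower in 4 of 4 arrays; adjusted p = 0.241 with an estimated correlation), and -0.0669 without the 4 arrays high in these transcripts, 2 of them saline LFD arrays. Npc1l1 was at -1.46 ± 0.57 and Slc2a2, a glucose transporter of the small intestine, at -0.92 ± 0.27. Interferon response genes averaged -0.18 ± 0.14, 20 of 21 below 0 (camera adjusted p = 0.000183, lower in 3 of 4), and cholesterol biosynthesis and uptake -0.19 ± 0.17 (camera adjusted p = 9.13e-05, lower in 3 of 4), with adjusted p of 0.791 and 0.841 with an estimated correlation. Without butyrate LFD 2 these means were -0.0979 and -0.0729. Gstm1, a glutathione transferase (0.29 ± 0.0881), was higher adjusted over the xenobiotic list alone. The other small p belonged to Zfp957, Adgrg1, Ube2h and B9d1 (higher) and Psmb8, Impact, Podxl and Exoc3l4 (lower), each in 4 of 4 arrays. No gene passed in limma, with 358 at an unadjusted p under 0.05, fewer than the 639.8 expected by chance. Camera called 8 lists, none of them called by fry or with an estimated correlation.

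On HFD each acid was compared with the 4 saline arrays of that diet. Under acetate the smooth muscle transcripts were lower, by -0.66 ± 0.23 on average with 10 of 10 below 0 (camera adjusted p = 2.08e-12, lower in 4 of 4 arrays; adjusted p = 0.0952 with an estimated correlation). Adjusted over the list alone 6 were lower, Myl9 (-1.07 ± 0.30), Tagln (-0.61 ± 0.18) and Des (-0.92 ± 0.31) among them. Without the 2 saline HFD arrays high in these transcripts the mean was -0.0654. For smooth muscle on HFD the SD was 0.712 under saline and 0.0817 to 0.219 under the acids. The ± 0.23, pooled over all 8 groups, is therefore too small for each acid against saline. PPAR-alpha targets averaged 0.27 ± 0.14 (camera adjusted p = 0.000127, higher in 4 of 4; adjusted p = 0.354 with an estimated correlation). Angptl4, an inhibitor of lipoprotein lipase, was at 0.85 ± 0.27 and higher adjusted over the list alone, and Pdk4, a kinase that restrains pyruvate oxidation, at 0.97 ± 0.39. Fatty acid oxidation averaged 0.13 ± 0.0849, 19 of 20 genes above 0 (camera adjusted p = 1.21e-06, higher in 3 of 4), cholesterol biosynthesis and uptake -0.26 ± 0.17, 20 of 20 below 0 (camera adjusted p = 7.02e-09, lower in 3 of 4), and endothelium 0.16 ± 0.0604 (camera adjusted p = 0.00018, higher in 4 of 4). Their adjusted p with an estimated correlation were 0.509, 0.484 and 0.167, and the cholesterol mean was -0.10 without saline HFD 4. The level of endothelium was 4.53 under saline and 4.69 under acetate, near the filter's log2 of 4.32, which limits it. The smallest p was that of Cnih2 (-0.47 ± 0.0876, adjusted p = 0.131), followed by Phldb2, Cd93 and Igkv8-30 (higher) and Tomm40l, Nelfe, Pop7, Med28, Myl9 and Tagln (lower), each in 4 of 4 arrays. Limma found 0 genes (1 with array weights), with 321 at an unadjusted p under 0.05, fewer than the 639.8 expected by chance. Camera called 13 lists, none called by fry or with an estimated correlation.

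Under propionate on HFD ribosomal protein transcripts were higher, by 0.16 ± 0.0495 on average with 36 of 38 above 0 (camera adjusted p = 1.21e-16, higher in 4 of 4 arrays; adjusted p = 0.507 with an estimated correlation). Adjusted over the list alone 7 were higher, Rps27 (0.46 ± 0.11), Rpl13 (0.35 ± 0.095) and Rpl24 (0.58 ± 0.16) among them. They moved with the small nucleolar RNAs, which averaged 0.62 ± 0.16 higher, with 53 of 55 above 0 and 34 at an unadjusted p under 0.01. Enzymes of the tricarboxylic acid cycle averaged -0.12 ± 0.0448 (camera adjusted p = 0.00193, lower in 4 of 4), 6 of 15 lower adjusted over the list alone, such as the citrate synthase Cs (-0.24 ± 0.0751) and Mdh2 (-0.17 ± 0.0558). Glycolysis averaged -0.12 ± 0.0577 (camera adjusted p = 0.011, lower in 4 of 4; 4 of 13 lower adjusted over the list alone), cholesterol biosynthesis and uptake -0.39 ± 0.17 (camera adjusted p = 1.87e-07, lower in 4 of 4) and smooth muscle -0.61 ± 0.23 (camera adjusted p = 0.000136, lower in 4 of 4). Without the 2 saline HFD arrays high in smooth muscle its mean was -0.0141, and without saline HFD 4 glycolysis was at -0.0801 and cholesterol biosynthesis and uptake at -0.23. These 4 lists had an adjusted p of 0.646 with an estimated correlation and 0.182 by fry.

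In the same comparison Hsd11b2, the enzyme that inactivates corticosterone in the colon, had the smallest p (-0.57 ± 0.12, adjusted p = 0.236, lower in 4 of 4 arrays), followed by Pdcd6ip, Castor1 and the phosphatase Dusp1 (-0.68 ± 0.17) lower and Stx16, Sncb, Rps27, Safb2, Mfsd6l and Dgkd higher. Cdkn1a, the cell cycle inhibitor, was lower adjusted over its list alone (-0.41 ± 0.13), the list of genes raised by inhibition of histone deacetylases, whose mean was -0.12 ± 0.10. That adjustment leaves out the other lists and comparisons. No single gene passed in limma (0 genes), with 1497 at an unadjusted p under 0.05, and 213 with array weights, 3 over all probe sets and 1 with the replicate number as a block. Camera called 11 lists, none of them called by fry or with an estimated correlation.

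Under butyrate on HFD markers of cells beneath the epithelium averaged higher, in part through butyrate HFD 1. Fibroblast genes averaged 0.42 ± 0.22, 10 of 10 above 0, with Col1a2 at 0.62 ± 0.23 (camera adjusted p = 2.11e-05, higher in 3 of 4 arrays). B and plasma cells averaged 0.54 ± 0.29 (camera adjusted p = 3.37e-05, 3 of 4), macrophages and dendritic cells 0.26 ± 0.13, with C1qb at 0.49 ± 0.19 (camera adjusted p = 0.000502, 4 of 4) and endothelium 0.17 ± 0.0604 (camera adjusted p = 0.000502, 3 of 4). Without butyrate HFD 1 these 4 means were 0.22, 0.36, 0.11 and 0.12. Endothelium (level 4.53 under saline, 4.70 under butyrate) and B and plasma cells (4.50 and 5.04) lie near the filter's log2 of 4.32, which limits both. Smooth muscle was at -0.53 ± 0.23 (camera adjusted p = 4.33e-09, lower in 4 of 4), with Tagln, Myl9 and Des lower adjusted over the list alone, but at 0.0635 without the 2 saline HFD arrays high in these transcripts. Under the estimated correlation the adjusted p were 0.401 for the first 3, 0.273 for endothelium and 0.273 for smooth muscle. The smallest p belonged to Csf2rb2, a cytokine receptor subunit (0.61 ± 0.13), H2-M3, the adaptor of Toll-like receptors Myd88 (0.23 ± 0.0563), Pdpn, Nanp, Antxr1, Gimap8 and Gna15 (higher) and Nit1 and Map1lc3a (lower), each in 4 of 4 arrays. The genes raised by inhibition of histone deacetylases, which butyrate inhibits in cultured cells, averaged -0.02 ± 0.10 (95% interval -0.23 to 0.18; camera adjusted p = 0.323). The count in limma was 0 genes (smallest adjusted p = 0.818), with 513 at an unadjusted p under 0.05, fewer than the 639.8 expected by chance. Camera called 12 lists, none called by fry or with an estimated correlation.

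**Figure D3:**
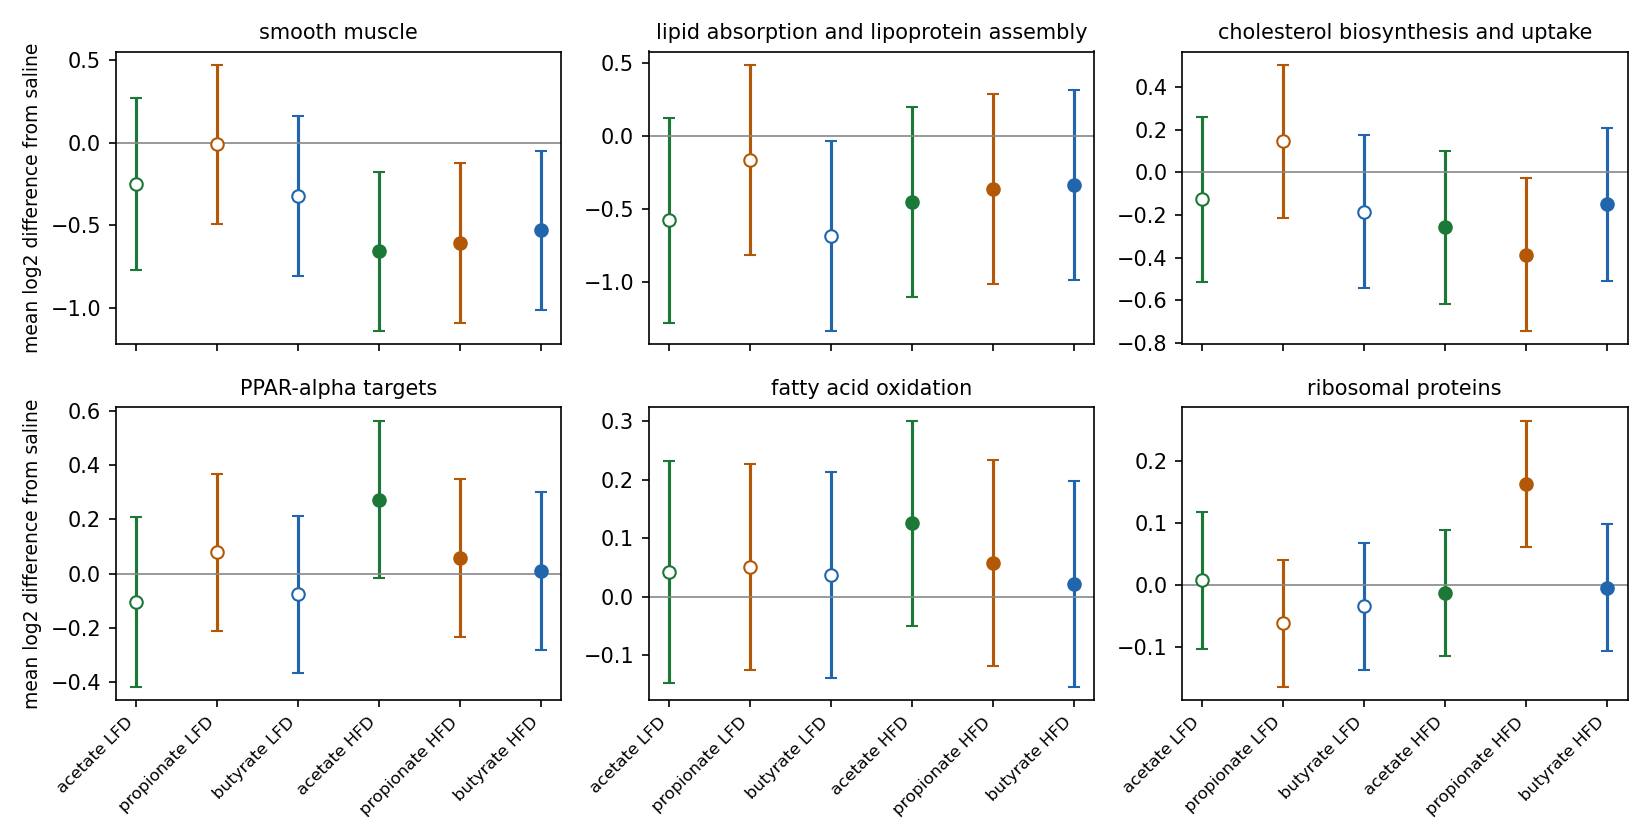
Mean log2 difference from saline (y axis) of 6 gene lists for each acid and diet (x axis; open LFD, filled HFD), with 95% intervals from the fit. The intervals pool the spread of all 8 groups. They are too narrow where saline varied more, as in smooth muscle on HFD (SD 0.712) and lipid absorption on LFD (SD 0.715). On HFD smooth muscle lies between -0.66 and -0.53 for the 3 acids, against saline arrays of which 2 are high in it, PPAR-alpha targets lie at 0.27 under acetate, and ribosomal proteins at 0.16 under propionate.

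Of the genes fixed beforehand as candidate targets of the acids, Angptl4, Pdk4, Cpt1a, the transporters Slc16a1 and Slc5a8 and the receptors Ffar2 and Ffar3, none passed in any of the 17 comparisons. Angptl4 ranged from -0.59 (butyrate against acetate on HFD) to 0.85 (acetate on HFD), with a lowest adjusted p of 0.0952 for diet over all infusions, where it stood at 0.39 ± 0.14. The range was -0.75 to 0.97 for Pdk4, -0.16 to 0.22 for Cpt1a, -0.18 to 0.18 for Slc16a1, -0.21 to 0.19 for Slc5a8, -0.18 to 0.26 for Ffar2 and -0.12 to 0.09 for Ffar3. The lowest value of Pdk4, butyrate against acetate on HFD, rests in part on butyrate HFD 1, at 6.69 against 7.91 to 8.07 on the other arrays of its group. The list of short-chain fatty acid receptors and transporters was called in no comparison.

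The series title asks whether the responses depend on dietary fat, which was tested as the difference between the response on HFD and that on LFD. Propionate gave the widest differences: ribosomal proteins responded 0.23 ± 0.07 more on HFD (camera adjusted p = 2.67e-15), 16 of 38 adjusted over the list alone, with Rpl24 at 0.93 ± 0.23 and Rps27 at 0.64 ± 0.16. Enzymes of short-chain fatty acid breakdown responded -0.28 ± 0.0791 (camera adjusted p = 0.000168; 5 of 14 lower adjusted over the list alone, Echs1 at -0.54 ± 0.15), those of the tricarboxylic acid cycle -0.19 ± 0.0634 (camera adjusted p = 0.00111; 7 of 15) and cholesterol biosynthesis and uptake -0.53 ± 0.24 (camera adjusted p = 3.3e-06). The first 3 of these lists had an adjusted p of 0.0688 by fry, and with an estimated correlation the 4 had 0.519, 0.519, 0.715 and 0.864. The small nucleolar RNAs moved alongside, 0.96 ± 0.23 higher with 52 of 55 above 0. The single genes with the smallest p were Brca2 (-0.95 ± 0.21), Hsd11b2 (-0.78 ± 0.17), Gtf2h4, Eral1, Ift20, Lgals12 and Slc25a11 (lower on HFD) and Rbis, Snrnp70 and Safb2 (higher), none past the threshold (adjusted p = 0.141 to 0.154). Limma found 0 genes, with 1643 at an unadjusted p under 0.05, and 101 with array weights, 11 with the replicate number as a block, 13 without propionate HFD 4 and 1 without the 4 arrays high in small-intestinal transcripts.

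For acetate, PPAR-alpha targets responded 0.38 ± 0.21 more on HFD than on LFD with 14 of 14 above 0 (camera adjusted p = 2.55e-06; 0.348 as the adjusted p with an estimated correlation), and interferon response genes 0.30 ± 0.21 more (camera adjusted p = 1.45e-07; 0.848 with an estimated correlation), or 0.19 without acetate LFD 3. Smooth muscle responded -0.41 ± 0.34 (camera adjusted p = 0.00114; 0.881 with an estimated correlation), and 0.19 without the 2 saline HFD arrays high in these transcripts. In limma 0 genes passed, with 108 at an unadjusted p under 0.05, fewer than the 639.8 expected by chance. The smallest p belonged to Mesp2 (-0.54 ± 0.14), Pop7, Cldn20, Prr16 and Ankrd10 (lower on HFD) and Pemt, Dedd2, Pcp2, Cybrd1 and Dcun1d1 (higher).

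For butyrate, interferon response genes responded 0.34 ± 0.20 more on HFD with 21 of 21 above 0 (camera adjusted p = 3.21e-06) and MHC class II genes 0.42 ± 0.36 more with 9 of 9 above 0 (camera adjusted p = 0.0107); with an estimated correlation both had an adjusted p of 1. The MHC class II mean was 0.22 without butyrate HFD 1 and 0.20 without the 4 arrays high in small-intestinal transcripts. Camera also called the markers of fibroblasts, of endothelium and of macrophages and dendritic cells upward in this comparison, as given in the closing sections. No gene passed in limma, with 291 at an unadjusted p under 0.05, fewer than the 639.8 expected by chance. The smallest p belonged to Pdpn (0.59 ± 0.16), Zbp1, a sensor of nucleic acids (0.64 ± 0.17), H2-M3, Taf7, Nanp, Sec24c, Cpxm2 and Tsen15 (higher on HFD) and Zfp108 and Nit1 (lower). Over the 3 acids camera called 19 list differences, and none was called by fry or with an estimated correlation.

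Across the 12795 genes the response to acetate on LFD correlated with that on HFD at a Pearson r of 0.354 (Spearman 0.271), each diet with its own saline arrays; 59.2% of the genes had the same sign. For the Pearson r the exact permutation test over 2450 relabellings of the arrays gave p = 0.0098, two-sided (Benjamini-Hochberg adjusted over the 3 acids 0.0294), while the Spearman value did not pass. The Pearson r was 0.110 (exact p = 0.586) without the 4 arrays high in small-intestinal transcripts, 0.230 (exact p = 0.149) without the 2 saline HFD arrays high in smooth muscle, and 0.165 (exact p = 0.267) without acetate LFD 1. Propionate gave -0.263 (Spearman -0.291; exact permutation p = 0.207, adjusted 0.207; 38.6% of genes with the same sign) and butyrate 0.279 (Spearman 0.159; exact permutation p = 0.141, adjusted 0.207; 54.7%). Without the 4 arrays high in small-intestinal transcripts propionate gave -0.413 (exact p = 0.0314). Genes are not independent replicates, so the arrays were permuted.

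The acids differ by chain length and were given at the same dose and time, so they were compared with each other directly. On HFD butyrate against propionate gave the only genes past the threshold. Myd88 (probe set 10597648) was 0.34 ± 0.0563 higher under butyrate (adjusted p = 0.0255) and Tdg, a DNA glycosylase of base excision repair, 0.55 ± 0.11 higher (adjusted p = 0.0492), each in 4 of 4 arrays. Another 6 genes were lower under butyrate, 4 of them small nucleolar RNAs, and each of the 6 is a small RNA or a gene model without a descriptive name. The small nucleolar RNAs as a set were 0.69 ± 0.16 lower under butyrate, in 4 of 4 arrays.

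Ribosomal proteins were 0.17 ± 0.0495 lower under butyrate than under propionate on HFD (95% interval -0.27 to -0.07; camera adjusted p = 5.23e-16, 4 of 4 arrays; 16 of 38 lower adjusted over the list alone). Tricarboxylic acid cycle enzymes were 0.16 ± 0.0448 higher (0.07 to 0.25; camera adjusted p = 0.00125, 4 of 4; 8 of 15 higher adjusted over the list alone, Idh3a at 0.43 ± 0.11), the only acid comparison with a list called by fry (adjusted p = 0.0472). With an estimated correlation the adjusted p were 0.413 and 0.684. Shq1, Pbrm1, Itpripl1 and Pdcd6ip (higher) and AY036118, Rps27, Clec2d and Snhg15 (lower) had the next smallest p, with adjusted p of 0.0533 to 0.0659. Limma found 8 genes, with 2217 at an unadjusted p under 0.05. The count was 53 with the stricter filter, 73 over all probe sets, 937 with array weights, 2 without the 4 arrays high in small-intestinal transcripts and 0 with the small nucleolar RNA mean as a covariate, and 0 to 585 (without propionate HFD 1) when single arrays were left out.

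Propionate against acetate on HFD rests on the same 4 propionate arrays as butyrate against propionate, so a shift in those arrays alone would move the same sets in both. Ribosomal proteins were 0.18 ± 0.0495 higher under propionate (0.07 to 0.28; camera adjusted p = 3.55e-17, 4 of 4 arrays; 17 of 38 higher adjusted over the list alone), alongside small nucleolar RNAs 0.70 ± 0.16 higher. Tricarboxylic acid cycle enzymes were at -0.14 ± 0.0448 (-0.23 to -0.04; camera adjusted p = 0.00166, lower in 4 of 4) and interferon response genes at -0.30 ± 0.14 (-0.59 to 0.000272; camera adjusted p = 0.00064, lower in 4 of 4). Under the estimated correlation the 3 lists had adjusted p of 0.46, 0.947 and 0.947. Taf11, the nuclear RNA Malat1 (0.49 ± 0.10), Rps28 (0.63 ± 0.13) and Rps27 (0.53 ± 0.11) had an adjusted p of 0.0576, and Stx4a, Snhg17, a host gene of small nucleolar RNAs (1.00 ± 0.22), Ccnl2, Rdm1, Eef1g and Rpl24 followed, all higher in 4 of 4 arrays. No single gene passed in limma (0 genes), with 1686 at an unadjusted p under 0.05, and 1202 with array weights, 72 with the replicate number as a block, 16 after quantile normalization and 0 to 147 (without propionate HFD 4) when single arrays were left out.

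For butyrate against acetate on HFD camera called 9 lists, none of them called by fry or with an estimated correlation. PPAR-alpha targets were at -0.26 ± 0.14 under butyrate (-0.55 to 0.03; camera adjusted p = 8.46e-05, lower in 4 of 4 arrays), Angptl4 at -0.59 ± 0.27, and fatty acid oxidation at -0.10 ± 0.0849 (-0.28 to 0.07; camera adjusted p = 2.34e-05, lower in 3 of 4). Both had adjusted p = 0.756 with an estimated correlation, and without butyrate HFD 1 they were at -0.16 and -0.0399. Smooth muscle differed by 0.13 ± 0.23 (-0.35 to 0.61; camera adjusted p = 0.55, 3 of 4 arrays). Limma found 0 genes, with 466 at an unadjusted p under 0.05, fewer than the 639.8 expected by chance. The smallest p belonged to Exosc2, Gimap9, Elac2, Pdpn, Cnih2 and Xxylt1 (higher) and P2rx4, Ube2b, Tsc1 and Ano10 (lower).

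On LFD no single gene passed between the acids, and the 95% intervals of the list means given here cross 0. Cell cycle genes were 0.30 ± 0.15 higher under propionate than under acetate, 25 of 26 above 0 (-0.00265 to 0.61; camera adjusted p = 1.54e-11, higher in 4 of 4 arrays), and 0.19 ± 0.15 higher under butyrate than under acetate (-0.11 to 0.50; camera adjusted p = 4.02e-08, 3 of 4). Cholesterol biosynthesis and uptake was 0.27 ± 0.19 higher under propionate than under acetate (-0.11 to 0.66; camera adjusted p = 4.37e-06, 4 of 4) and -0.33 ± 0.17 under butyrate against propionate (-0.69 to 0.03; camera adjusted p = 3.94e-10, lower in 3 of 4), with 20 of 20 genes on one side in each. With an estimated correlation these had adjusted p of 0.649, 0.98, 0.649 and 0.438. Leaving out acetate LFD 2 gave 0.11 for the cell cycle under butyrate against acetate, leaving out acetate LFD 1 gave 0.0902 for cholesterol under propionate against acetate, and leaving out butyrate LFD 2 gave -0.22 for cholesterol under butyrate against propionate. Limma found 0 genes in each of the 3 comparisons, with 473 (propionate against acetate), 179 (butyrate against acetate) and 463 (butyrate against propionate) at an unadjusted p under 0.05. Each count is lower than the 639.8 expected by chance.

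The smallest p for propionate against acetate on LFD belonged to Fcrlb, Stmn4, Gng10, Hic2, Msgn1, Gh, Arhgap44 and the clock gene Ciart (-1.14 ± 0.31), lower, and Depdc1a and Lrrc28, higher. For butyrate against acetate they were Olfr91, Nat8f1 and Fbln5 (higher) and Gpr55, Gng10, Pelo, Gda, Gsdmcl-ps, Esam and Coasy (lower). For butyrate against propionate they were Zfp593 and Rasl10b (higher) and Gsdmcl-ps (-0.81 ± 0.19), Zfp951, Fgfbp1, Lpin1, a phosphatidate phosphatase (-0.78 ± 0.21), Tnfsf13b, Bcl6, Cars2 and Blm (lower). Each lay on that side in 4 of 4 arrays, except Pelo in 3 of 4, and the adjusted p were 1, 1 and 0.999.

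Responses of 2 acids against the same saline arrays share those arrays, so part of any likeness between them is chance. Across genes their Pearson r was 0.400 to 0.621 on LFD and 0.228 to 0.499 on HFD. Simulated unchanged groups that share a simulated control group gave means of 0.445 to 0.501, and each observed value lay inside its simulated 95% range. The simulated controls were drawn from all 31 arrays, so they do not carry the spread of the saline arrays. In smooth muscle on HFD the SD was 0.712 under saline and 0.0817 to 0.219 under the acids. The covariances differed from the simulated ones by -0.00432 to 0.000521. With the 4 saline arrays split 2 and 2, so that no array is shared, the mean r was -0.191 to -0.00216.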

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

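The tests of the small-intestinal and smooth muscle transcripts, and the list means without arrays, were chosen after the results were seen. The small nucleolar RNAs were picked as a set after their values were seen, while their 2 tests and the other splits of the arrays were written before the outcome of each was known. Several of the former were also revised once their first outcome was known. The enterocyte test was first run on a wider set of markers and then limited to those not already looked at, and the Paneth cell test likewise; neither outcome changed. The nerve cell test first counted against the muscle layer, and was reread as undecided because its markers lie near the floor. The first test of an acid effect on smooth muscle counted against it, and was replaced because leaving out the highest saline arrays forces the difference towards 0. The test of a saline effect on small-intestinal transcripts first counted against it, was reread as undecided because the arrays it counts are those that define the pattern, and was then parted into an effect in every saline sample and in some.

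Small nucleolar RNAs averaged 7.75 under propionate on HFD against 7.12 under saline, a difference of 0.62 ± 0.16. A shift in RNA make-up between arrays, such as one from RNA quality or isolation, is a candidate explanation: across 12237 genes outside the small RNAs, the propionate response correlated with the within-group slope on the small nucleolar RNA mean in the other 7 groups at 0.615, where the central 95% of permuted slopes gave -0.485 to 0.428. More transcription of the host genes is not decided: their median difference was 0.0565 over 28 hosts, above the central 95% of random sets (-0.117 to -0.00193) but under the 0.1 set beforehand. It was 0.145 over the 13 hosts that are ribosomal protein genes and 0.0373 over the others, against 0.564 for all 55 small nucleolar RNAs. Of these 55, 32 lie within the 28 hosts. The host gene Snhg17, higher under propionate than under acetate on HFD, is not among the 28, so the median does not cover every host. An effect of propionate on HFD itself stays open and cannot be told apart from such a shift, as the 4 arrays of that group lie at 7.40 to 8.00, above those of the other groups except saline LFD 1 (7.79) and acetate LFD 1 (7.58).

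Smooth muscle transcripts were lower with each acid on HFD, where saline HFD 1 and 2 lie at 6.76 and 6.56. More of the muscle layer in those scrapings may be the source, but the deviations of smooth muscle and nerve cell markers from the group means correlated at only 0.0502 over the 31 arrays (Spearman -0.00806, permutation p = 0.79 and 0.967, adjusted over 2 relations 0.79 and 0.967; -0.154 without saline HFD 1 and 3, whose deviations were farthest out). The 5 nerve cell markers average 4.86, near the floor, so this decides nothing. For an effect of the infused acids, 2 of the 4 saline HFD arrays lay above the highest of the 12 acid arrays (5.76). This falls between the bounds for either answer, which were set after the values were seen. The 2 arrays counted are those that define the pattern, so the count decides nothing. Without those 2 arrays the differences were -0.0654 for acetate, -0.0141 for propionate and 0.0635 for butyrate, which is a description and not a test.

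Small-intestinal transcripts were high in saline LFD 2 and 3, saline HFD 2 and propionate LFD 2. RNA of small-intestinal enterocytes in those samples is a candidate explanation: each of the 4 arrays was among the 4 highest of 31 for at least 6 of 11 enterocyte markers outside the lipid list. For Paneth cell RNA the lowest number was 0 of 3 markers, too few to decide. The Paneth cell genes Lyz1 and Defa24, looked at earlier and so not counted, were high in these 4 arrays (8.92 to 10.95 and 7.32 to 9.63, at most 8.88 and 5.25 elsewhere), and this explanation stays open. An effect of saline infusion in every sample given it was not seen. Of the 8 saline arrays 5, at 6.61 to 6.66, lay within the range of the acid arrays but the highest (6.32 to 7.03). The highest of all was an acid array, propionate LFD 2 (8.12). An effect of saline infusion in some of the samples given it stays open: the 3 of 8 saline arrays above the range of those acid arrays are among the 4 that define the pattern. Both counts follow from the arrays that define the pattern, so they describe it and decide nothing more. No other biological explanation was tested.

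Of 329 group values tested 20 had 1 array far from the other 3 of its group, where chance gives about 1 in 20 groups, here 16.4. In the lipid absorption list these were propionate LFD 2 (8.12) and saline HFD 2 (7.91). Interferon response was high in saline HFD 4 (6.85) and butyrate HFD 1 (7.02), and MHC class II in propionate HFD 1 (7.18). Acute inflammation was high in propionate LFD 2 (4.99), tight junctions low in acetate HFD 2 (9.37), and ribosomal proteins low in saline HFD 4 (10.54) and propionate HFD 4 (10.67). Fibroblasts were high in propionate LFD 3 (6.55), endothelium in propionate HFD 1 (4.67), B and plasma cells in saline HFD 1 (5.10) and propionate HFD 1 (5.31), and adipocytes in butyrate HFD 4 (6.40). Small nucleolar RNAs were low in propionate LFD 4 (6.78). Pdk4 was low in butyrate HFD 1 (6.69), Angptl4 high in saline HFD 3 (6.02), Cpt1a low in acetate HFD 2 (10.94), Ffar2 low in saline LFD 3 (6.44) and Ffar3 high in butyrate LFD 2 (5.05).

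By the test of the difference with camera at the preset correlation, 19 lists responded differently on HFD and LFD. For acetate these were fatty acid oxidation (0.083), PPAR-alpha targets (0.38), interferon response (0.30), acute inflammation (-0.33), smooth muscle (-0.41) and adipocytes (0.43). For propionate they were short-chain fatty acid breakdown (-0.28), the tricarboxylic acid cycle (-0.19), cholesterol biosynthesis (-0.53), the cell cycle (-0.30), ribosomal proteins (0.23), goblet cells (0.30), tuft cells (0.19) and smooth muscle (-0.60). For butyrate they were interferon response (0.34), MHC class II (0.42), fibroblasts (0.40), endothelium (0.19) and macrophages and dendritic cells (0.25). None was called with an estimated correlation or by fry. Endothelium and acute inflammation also lie near the filter's log2 of 4.32. Without the 2 saline HFD arrays high in smooth muscle, that list was at 0.19 for acetate and -0.00522 for propionate. Without acetate LFD 1 acute inflammation was at 0.000366, without acetate LFD 2 fatty acid oxidation at 0.0180, without saline LFD 1 adipocytes at 0.17, and without propionate LFD 3 goblet cells at 0.19. Without butyrate HFD 1 MHC class II was at 0.22, fibroblasts at 0.20 and macrophages and dendritic cells at 0.10.

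With each count taken alone, other splits of the same arrays excluded chance for diet over all infusions. There 1 of 100 splits, the real one, gave 345 genes (highest other 1) and 1216 genes at an unadjusted p under 0.01 (highest other 629). For the propionate difference between diets at an unadjusted p under 0.01 (515 genes) chance was excluded only when this count is taken alone, with 4 of 100 splits as large and 814 in the highest other. Neither the share for diet nor that for propionate is adjusted over the 17 comparisons counted in this way, and 100 splits cannot give a share under 1 of 100. Chance could not be excluded for the 8 genes of butyrate against propionate on HFD (2 of 35 splits, highest other 59).

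At an unadjusted p under 0.01 chance could not be excluded for diet under saline (185 genes, 9 of 35 splits, highest other 781). On LFD it could not for acetate (25, 35 of 35, 870), propionate (62, 23 of 35, 224) and butyrate (40, 32 of 35, 720). On HFD it could not for acetate (48, 21 of 35, 464), propionate (427, 6 of 35, 1238) and butyrate (96, 10 of 35, 671). Nor could it for the differences between diets of acetate (15, 99 of 100, 666) and butyrate (45, 87 of 100, 510). Among acids on LFD the same held for propionate against acetate (71, 9 of 35, 287), butyrate against acetate (14, 35 of 35, 619) and butyrate against propionate (77, 15 of 35, 369), and on HFD for propionate against acetate (523, 4 of 35, 1561), butyrate against acetate (45, 22 of 35, 150) and butyrate against propionate (781, 4 of 35, 1166). Splits that call several times the real count point to a structure of the samples, and what that structure is was not tested.

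For the number of lists called by camera chance could be excluded in no comparison. The median over the other splits was 5 to 11 lists, so camera at the preset correlation often calls lists without the real grouping. Diet over all infusions had 13 lists (29 of 100 splits, highest other 20) and diet under saline 13 (2 of 35, 13). On LFD acetate had 13 (8 of 35, 17), propionate 8 (23 of 35, 18) and butyrate 8 (26 of 35, 17), and on HFD 13 (5 of 35, 16), 11 (8 of 35, 20) and 12 (13 of 35, 16). The differences between diets had 6 for acetate (87 of 100, 17), 8 for propionate (69 of 100, 18) and 5 for butyrate (95 of 100, 19). Among acids on LFD there were 6 for propionate against acetate (33 of 35, 17), 2 for butyrate against acetate (35 of 35, 18) and 7 for butyrate against propionate (31 of 35, 19), and on HFD 5 (19 of 35, 13), 9 (21 of 35, 14) and 8 (25 of 35, 15).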

How the results depend on the processing

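Leaving out the 4 arrays high in small-intestinal transcripts or the 2 high in smooth muscle, the small nucleolar RNA covariate and the list means without arrays were chosen after the result was seen. Of 5483 alternative values for the 224 genes and comparisons whose direction the report gives none reversed, 5143 kept direction and side of the threshold, 200 no longer passed and 140 newly passed. A gene that passed in neither fit counts as kept, and only diet over all infusions and butyrate against propionate on HFD had genes that passed. Of the 345 genes for diet, 115 still passed without the 2 saline HFD arrays and 74 over all probe sets. The naming rule covers 947 genes and comparisons, panel and list members included, and 225 of their 21976 values reversed, over 93 pairs that had not passed: 140 without single arrays, 23 with the covariate, 20 without the 4 arrays, 18 without the 2, 14 with array weights, 8 after quantile normalization and 2 with the block. The largest of these pairs was Apoa4 under butyrate on LFD (-1.86, and 0.26 without the 4 arrays). The 76 list means were judged against the spread of arrays within groups, a bound that 1 array left out can hardly reach. Of their 1173 alternative values 1164 lay within it, which does not make those means stable, 4 moved further and 5 reversed. Smooth muscle became -0.163 for diet under saline, 0.0635 for butyrate on HFD and 0.186 for the acetate difference between diets without the 2 arrays, lipid absorption under acetate on LFD 0.0411 without the 4, and the acetate difference in acute inflammation -0.544 to 0.000366 without single arrays. For diet over all infusions the 345 genes became 1788 with array weights, 106 over all probe sets, 559 without the 4 arrays and 115 without the 2; no filter gave 253, the stricter filter 455 and quantile normalization 387. Single arrays left out gave 127 to 1027 genes: 127 without acetate LFD 3, 137 and 171 without butyrate HFD 3 and 4, 150, 151 and 692 without saline HFD 1, 3 and 4, 156 and 228 without acetate HFD 1 and 4, 158 and 745 without acetate LFD 2 and 1, 178 without saline LFD 2 or 4, 187, 211 and 754 without butyrate LFD 3, 1 and 4, 202 and 799 without propionate HFD 3 and 1, 718 without butyrate HFD 2 and 1027 without saline LFD 3. Diet under saline gave 2 genes without the 4 arrays, and acetate on HFD 1 with array weights. Propionate on HFD gave 213 with array weights, 3 over all probe sets and 1 with the replicate block. Its difference between diets gave 101 with array weights, 11 with the block, 1 without the 4 arrays and 0 to 13 without single arrays (13 without propionate HFD 4). Propionate against acetate on HFD gave 11 with the stricter filter, 1202 with array weights, 5 over all probe sets, 16 after quantile normalization, 72 with the block, 16 without the 2 arrays and 0 to 147 without single arrays (9, 132 and 147 without propionate HFD 1, acetate HFD 2 and propionate HFD 4). Butyrate against propionate on HFD gave 53 with the stricter filter, 2 without the intensity trend, 2 with robust moderation, 937 with array weights, 73 over all probe sets, 21 after quantile normalization, 64 with the block, 2 without the 4 arrays and 0 with the covariate. Without single arrays it gave 0 to 585: 585 and 66 without propionate HFD 1 and 4, 1 without butyrate HFD 3, and 0 without propionate HFD 2 or 3 or butyrate HFD 1, 2 or 4. The replicate numbers were not taken to pair the arrays, as 42 of 105 same-number pairs, not all, correlated over 0.1 and 10 of 31 arrays correlated best, on average, with their own number. Same-number pairs averaged 0.0408 against -0.0135, with 0.116 among arrays numbered 2 and 0.00854 to 0.0174 for the other numbers. The correlation of the acetate responses (0.354) was 0.271 by Spearman (exact p = 0.0531), 0.110 without the 4 arrays, 0.230 without the 2, and 0.165 to 0.398 without single arrays (0.165 and 0.292 without acetate LFD 1 and acetate HFD 4, 0.195 without saline HFD 2, 0.292 without saline LFD 3, all no longer past the threshold). Propionate gave -0.413 without the 4 arrays and -0.358 to -0.0681 without single arrays (-0.358 without saline HFD 2, exact p = 0.0457), and butyrate 0.0678 to 0.38 (0.38 without saline HFD 3, exact p = 0.0343). With the stricter filter the shared-control r on HFD was 0.272 for acetate with propionate and 0.102 for propionate with butyrate. Lists called by camera fell to 0 in all 17 comparisons with an estimated correlation, and fry called 7 for diet, 6 of them among the 13 called by camera, 1 for butyrate against propionate on HFD and 0 elsewhere. The stricter filter gave 8 lists for diet under saline, 5 and 6 for propionate on LFD and HFD, 5 for butyrate on HFD, 1 for its difference between diets, 11 for butyrate against propionate on LFD and 3 for propionate against acetate on HFD. Without the 4 arrays acetate, propionate and butyrate on LFD gave 7, 5 and 5, and without the 2 arrays butyrate on HFD 7. The covariate gave 5 for the propionate difference between diets, 1 for butyrate against acetate on LFD and 9 for propionate against acetate on HFD. No filter gave 1 for butyrate against acetate on LFD and 13 for butyrate against propionate on HFD, and the block 1 for butyrate against acetate on LFD. The cause was not tested. Signal over background limits the dim genes, of which the filter removes only a part, as a gene that reached it on 3 arrays was kept. Tested B and plasma cell genes, for example, averaged 4.27 on saline HFD 2, under the filter's log2 of 4.32.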

Other observations

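The relation of smooth muscle with fibroblasts and the look at adipocyte and colon position markers were chosen after the values were seen. Adipocyte transcripts were high in butyrate LFD 2 (mean log2 level 7.30) and saline LFD 1 and 2 (7.14 and 6.87). The same 3 arrays were low in markers of the distal colon, at 5.70, 5.75 and 5.93, as was acetate LFD 1 at 5.63.

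Over the 31 arrays, deviations from the group means of smooth muscle and fibroblast transcripts correlated at a Pearson r of 0.447 and a Spearman rho of 0.49 (permutation p = 0.0119 and 0.00552, adjusted over 2 relations 0.0238 and 0.011). The r was 0.474 without saline HFD 1 and 3, the 2 arrays whose deviations from the group mean in smooth muscle were farthest from the median.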
